A study of Homo sapiens with 6 samples.

How the data were processed

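RNA-seq values of 3 libraries of H1 cells and 3 libraries of hEMP cells were analysed, grouped as the labels give them. Per the labels, total RNA was amplified with the NuGEN Ovation kit, made into libraries with PrepX reagents and sequenced as paired ends on an Illumina HiSeq. The processing notes of the authors name STAR 2.3.0, HTSeq and GRCh37, without the annotation release, the use of strand or the formula of the values. The deposited values are taken as RPKM, read density scaled to gene length and library size, computed by the authors. This unit was inferred from the values, since the header names none. Multiplied by exon lengths from GENCODE by Ensembl identifier, the values of 15539 of 15862 genes with a reference length came to whole reads in every library, within a tolerance of 0.05. For 60.4% of them more than 1 whole solution existed and the one nearest to the reference length was taken, so the recovered reads are estimates. On a simulated table of 4000 genes, 99.8% of the recovered genes had exactly the true reads. The simulated reference lengths were only slightly off the true ones, by a random factor. The error of the real lengths is not known, so that rate need not hold for these data. The reference annotation is on a later genome build than that of the authors, so no coordinates are given. Whether reads or read pairs were counted is not stated.

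The recovered reads per library ran from 6987499 to 12513777, and the detection floor was taken as 3 reads. Floors cover counting error only, since amplified reads are not independent molecules. Of 16321 genes listed, 241 were at 0 in all 6 libraries.

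Genes with at least 1 RPKM in at least 3 libraries were tested, 10146 in all. The values were analysed as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, using an empirical Bayes fit with a mean-variance trend, no block and two-sided tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount of 1 sets the size of log2 changes for genes near 0 in a group. Errors beside levels are SDs over 3 libraries, and those beside log2 changes are SEs from limma. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. On simulated data of the same layout, 200 of 10146 genes were moved by a log2 change of 0.5, 1 or 2, and a list of 20 by 0.5. Of the 200, 16.2% of those moved by 0.5 were called, 93.9% of those moved by 1 and 100% of those moved by 2. Among the calls, 5.8% were unchanged genes. Far more genes, 5087, were called in the real data, so these rates need not hold there.

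Before the data were examined, 34 gene lists were fixed, holding 609 genes: pluripotency, epithelial junction and identity, EMT and mesenchymal, extracellular matrix, primitive streak and nascent mesoderm, lateral plate and early cardiac mesoderm, paraxial mesoderm and somite, intermediate mesoderm, hemato-endothelial, blood cell, mesenchymal progenitor surface, definitive endoderm, neural ectoderm, neural crest, trophoblast and amnion, WNT feedback and target, BMP response, Nodal and activin response, FGF and ERK feedback, Notch pathway, HOX and CDX, DNA replication and S phase, mitosis, cell cycle inhibitor, p53 target, sterol synthesis, glycolysis, hypoxia response, DNA and histone methylation, imprinted genes, immediate early and heat shock, mitochondrially encoded, ribosomal protein and replication-dependent histone genes. The 32 lists with at least 3 tested members were compared with the other genes by camera with an inter-gene correlation of 0.01, adjusted over the lists. Of these, 19 passed, and 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05. With an estimated correlation camera takes its degrees of freedom from the 6 libraries and not from the genes. It then has little power with so few libraries, so a list that failed there is not shown to be unchanged. Members were counted with adjustment over all tested genes and over the list alone.

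Genes were named by a rule with 3 parts. The first held 17 index genes, of which 16 had a value. The second held the 10 highest and 10 lowest genes by log2 change among those that passed, had a mean of at least 10 RPKM in the higher group and had no overlap between the groups. The third held, for each list, up to 4 members with the largest changes among those that passed, and the most highly expressed member that did not. A few genes that the rule names are not reported here.

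The alternatives were median-of-ratios and upper-quartile scaling, scaling without mitochondrial, ribosomal protein and histone genes, no filter and a filter at 5 RPKM, pseudocounts of 0.1 and 5, a replicate block, leaving out each library, a test against a log2 change of 1, and camera with an estimated correlation or with ranks. Added after the data were seen were limma-voom on the recovered reads and the removal of a GC and length trend from each library by loess with a span of 0.5, for 10045 genes, and camera on the lists without the sort markers. The library sizes given to limma-voom came from median-of-ratios factors of the recovered reads. Its results therefore carry that kind of scaling and are not a separate check of it. The planned count-based tests were not run because the values are not counts. Genes with antisense partners or close copies were kept, and genes absent from the table were not analysed here.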

Results

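The transcriptomes of undifferentiated and early mesodermal human cells were compared by RNA-seq in 6 libraries. H1, an established human embryonic stem cell line, was sampled as 3 libraries of cells grown undifferentiated on Matrigel in mTeSR. The hEMP libraries, also 3, came from H1 cells moved to X-Vivo 15 medium with BMP4, VEGF and bFGF at 10 ng/mL each for 3.5 days, with activin A at the same dose on day 1. These cells, called human early mesodermal progenitors, were then sorted as negative for CD326 and positive for CD56. Each library gave a value in RPKM, a read density scaled to gene length and library size, for 16321 genes, of which 16080 were above 0 in at least 1 library. The reads behind these values were estimated at 8618535, 8616494 and 8703636 in H1 replicates 1 to 3. They were estimated at 11433158, 6987499 and 12513777 in hEMP replicates 1 to 3. For a gene of 2 kb, 3 reads corresponded to between 0.098 and 0.162 RPKM, so differences below that level were not detectable at this depth. The group explained most of the variance across the 10146 genes tested, with 85.2% of it on a first principal component that parted H1 from hEMP. A second component, with 7.7%, set H1 replicate 2 (score -26.5) apart from H1 replicates 1 and 3 (11.2 and 16.6). The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries only.

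The single comparison, hEMP against H1, asked how transcripts differ between human embryonic stem cells and the early mesodermal cells made from them. Medium and added factors differed with the group, and the labels name a sort for hEMP only. Their effects cannot be told apart from a change of cell state. Transcripts of the lateral plate mesoderm regulator HAND1 (ENSG00000113196) went from 0.191 ± 0.0252 to 183 ± 24.3 RPKM and those of the mesenchymal transcription factor gene SNAI2 (ENSG00000019549) from 0.682 ± 0.151 to 145 ± 21.2 RPKM (mean ± SD, n = 3 throughout). Those of the pluripotency regulators SOX2 (ENSG00000181449) and NANOG (ENSG00000111704) fell from 41.7 ± 8.25 to 1.52 ± 0.525 RPKM and from 23.9 ± 3.27 to 1.45 ± 0.388 RPKM. All 18 tested genes of a list of lateral plate and early cardiac mesoderm rose, as did all 13 of a list of BMP response genes. In contrast, 14 of 17 pluripotency genes and 14 of 19 epithelial genes fell. Members of lists for the haematopoietic and endothelial lineage and for the primitive streak, the embryonic site where mesoderm forms, also rose, 16 of 17 and 13 of 14. A gene near 0 in H1 passed the filter of 1 RPKM in 3 libraries only if it was higher in hEMP. That filter in part set these counts of rises.

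Over all genes, limma-trend on log2(RPKM + 1) with Benjamini-Hochberg adjustment called 5087 of 10146 genes changed at an adjusted p under 0.05, 3252 higher and 1835 lower in hEMP. Of the 10146 genes tested, 6022 had no overlap between the 3 values of one group and the 3 of the other, against 10% of genes by chance. The median log2 change of all tested genes was 0.14, so that changes near this size lie on the common shift. The share of higher genes among those called rested on the scaling. It was 63.9% with the deposited scaling, 51.0% with median-of-ratios scaling and 45.4% with upper-quartile scaling, which called 2907 genes lower. A change of at least 2-fold was estimated for 1770 of the called genes, 1166 higher and 604 lower. That count was 740 when the test itself was against a log2 change of 1, 651 with a pseudocount of 5, 2488 with a pseudocount of 0.1 and 2433 by limma-voom. The pseudocount of 1 compresses the log2 changes of genes near 0 in H1. Genes are named below by a rule set before the data were examined, with some exceptions. KRT8, KRT18, VCAN, THY1, HHEX, FOXA3, SOX17, APOA2, ETV4, NRARP, TYMS, ADM, SNRPN, GRB10 and HSPH1 were chosen after their values were seen.

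The surface markers used for the sort moved with the gate, which makes them a check of the labels rather than a finding. EPCAM, which encodes CD326, fell from 63.8 ± 6.61 to 6.67 ± 1.81 RPKM (log2 change -3.10 ± 0.18, SE, adjusted p = 6.3e-07 by limma). NCAM1, which encodes CD56, went from 0.222 ± 0.0228 to 7.64 ± 0.621 RPKM (log2 change 2.82 ± 0.13, adjusted p = 1.2e-07). Among cadherins, CDH1, the epithelial form, fell from 61.1 ± 17.5 to 6.25 ± 1.28 RPKM, and CDH2, the form found on mesenchymal and neural cells, rose from 12.6 ± 1.97 to 48.8 ± 6.84 RPKM. The primitive streak transcription factors MIXL1 and EOMES rose from 0.325 ± 0.263 to 35.2 ± 5.23 RPKM and from 0.198 ± 0.0961 to 29.3 ± 4.94 RPKM. T, the brachyury gene, and MESP1, a regulator of early cardiac mesoderm, also rose. T was at 0.0679 ± 0.0413 RPKM in H1 and 2.82 ± 1.1 RPKM in hEMP, and MESP1 was at 0.0248 ± 0.0215 RPKM in H1 and 3.68 ± 0.288 RPKM in hEMP. FOXF1 and GATA4, transcription factors of lateral plate mesoderm, rose from 0.0468 ± 0.0221 to 22.2 ± 4.14 RPKM and from 0.0935 ± 0.114 to 19.2 ± 3.34 RPKM. Of the receptors, PDGFRA rose from 0.566 ± 0.42 to 39.4 ± 9.02 RPKM, and the VEGF receptor gene KDR, already present in H1, rose 5.29-fold from 39.9 ± 11.2 to 211 ± 27.3 RPKM. POU5F1, a further index gene, was not analysed here.

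**Figure D1:**
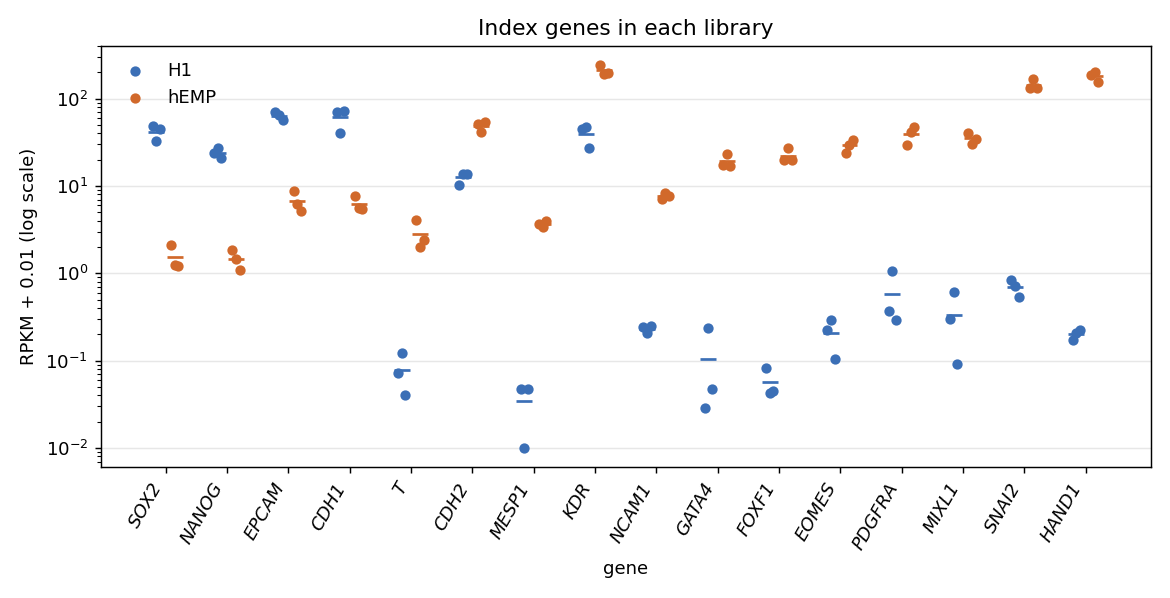
RPKM plus 0.01 on a log axis for 16 index genes in each of the 3 H1 and 3 hEMP libraries, with points for libraries and bars for group means, ordered by log2 change. SOX2, NANOG, EPCAM and CDH1 lie higher in every H1 library than in any hEMP library, and the other 12 genes lie higher in every hEMP library.

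The genes with the 10 largest increases on the log2(RPKM + 1) scale, among those at 10 RPKM or more in the higher group, included HAS2, which encodes a hyaluronan synthase (1.13 ± 0.475 RPKM in H1 and 364 ± 48.9 RPKM in hEMP, log2 change 7.44 ± 0.18, adjusted p = 4e-09). APLNR, the apelin receptor gene, was at 0.378 ± 0.234 RPKM in H1 and 226 ± 46.8 RPKM in hEMP (log2 change 7.36 ± 0.18), and HAND1, HAPLN1 and SNAI2 were also among them. The order of genes near 0 in H1 depends on the pseudocount, and over the alternatives the log2 change reached 8.28 for HAS2 and 9.55 for HAND1. HAPLN1, whose product links hyaluronan to proteoglycans, went from 0.547 ± 0.181 to 166 ± 47.3 RPKM. NTS, the neurotensin gene, reached the highest level of the 10 in hEMP, from 11.4 ± 7.72 to 666 ± 180 RPKM. The remaining genes were CFC1, FAM89A, CER1 and GATA6, with log2 changes between 5.66 and 5.86. CFC1 has a near-identical copy, CFC1B, with which reads may be shared. HAS2 and GATA6 have antisense partners whose reads cannot be told apart without strand information. The 10 largest decreases on the same scale included IDO1, a tryptophan-degrading enzyme (30.1 ± 8.37 RPKM in H1 and 0.442 ± 0.347 RPKM in hEMP, log2 change -4.42 ± 0.23, adjusted p = 3.5e-07), and SOX2. AASS, an enzyme of lysine breakdown, fell from 294 ± 44.1 to 23.4 ± 6.38 RPKM. The deubiquitinase gene USP44 fell from 64 ± 2.77 to 4.54 ± 1.35 RPKM, and the laminin receptor gene ITGA6 from 44.7 ± 6.47 to 3.36 ± 1.11 RPKM. MT1H, SCGB3A2, LECT1, PTPRZ1 and NANOG completed the 10, with log2 changes between -3.86 and -3.35. MT1H belongs to the metallothionein family of close copies, and NANOG has processed pseudogenes, so their levels are less certain.

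Pluripotency genes fell in hEMP, with 14 of 17 tested members lower, none higher and a median log2 change of -1.89 (15 adjusted over the list alone; camera adjusted p = 1.6e-09, and adjusted p = 0.19 with an estimated correlation). Besides SOX2, NANOG and USP44, TERF1, which encodes a telomere-binding protein, fell from 153 ± 41.6 to 15.6 ± 3.96 RPKM. LIN28B, a repressor of let-7 microRNAs, did not pass (68.9 ± 2.4 RPKM in H1 and 69.3 ± 5.24 RPKM in hEMP, adjusted p = 0.97). Epithelial junction and identity genes were lower for 14 of 19 members and higher for 3, with a median of -1.48 (18 adjusted over the list alone; camera adjusted p = 3.2e-06, and adjusted p = 0.23 with an estimated correlation). Without the sort marker EPCAM, which this list holds, 13 of 18 were lower (camera adjusted p = 1.7e-05, and adjusted p = 0.28 with an estimated correlation). The tight junction gene OCLN fell from 13.8 ± 0.446 to 2.22 ± 0.409 RPKM. The 3 that rose were the keratin genes KRT19, KRT8 and KRT18, and KRT8 and KRT18 have many pseudogenes. KRT19 rose from 12.4 ± 2.48 to 130 ± 22.5 RPKM, KRT8 from 7.42 ± 1.02 to 35.6 ± 3.88 RPKM and KRT18 from 31.2 ± 3.61 to 57 ± 6.96 RPKM. The desmosome gene DSP did not pass (33.2 ± 10.7 RPKM in H1 and 47.4 ± 5.25 RPKM in hEMP, adjusted p = 0.064).

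Genes of mesenchymal identity and of epithelial-to-mesenchymal transition rose, 15 of 16 with a median log2 change of 2.63 (15 adjusted over the list alone; camera adjusted p = 2.4e-09, and adjusted p = 0.19 with an estimated correlation). CDH11 went from 0.949 ± 0.311 to 72.8 ± 2.89 RPKM, SNAI1 from 0.914 ± 0.394 to 37.1 ± 1.3 RPKM and ZEB2 from 0.152 ± 0.131 to 13 ± 1.06 RPKM. AXL, a receptor tyrosine kinase gene, did not pass (17 ± 6.58 RPKM in H1 and 19.2 ± 4.19 RPKM in hEMP). Of 23 extracellular matrix genes, 19 rose and 1, VCAN, fell, with a median of 1.70 (20 adjusted over the list alone; camera adjusted p = 4e-06, and adjusted p = 0.22 with an estimated correlation). The fibrillar collagen genes COL5A1 and COL5A2 rose from 1.17 ± 0.165 to 34.2 ± 5.03 RPKM and from 1.63 ± 0.99 to 40 ± 6.57 RPKM. The laminin gene LAMB1 did not pass (16.4 ± 7.66 RPKM in H1 and 24.4 ± 3.37 RPKM in hEMP). Surface markers of mesenchymal progenitors rose for 10 of 11 members (11 adjusted over the list alone; camera adjusted p = 0.00051, and adjusted p = 0.22 with an estimated correlation). The fibronectin receptor gene ITGA5 rose from 1.13 ± 0.0723 to 27.8 ± 2.88 RPKM and PDGFRB from 0.949 ± 0.0309 to 7.28 ± 0.682 RPKM. Without the sort marker NCAM1, which this list holds, 9 of 10 rose (camera adjusted p = 0.0022, and adjusted p = 0.30 with an estimated correlation). THY1, which encodes CD90, was the 1 tested member that fell, from 15.9 ± 2.87 to 6.43 ± 1.28 RPKM. Another 3 of the 15 genes of this list were below the filter, all 3 under 1 RPKM in every library.

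**Figure D2:**
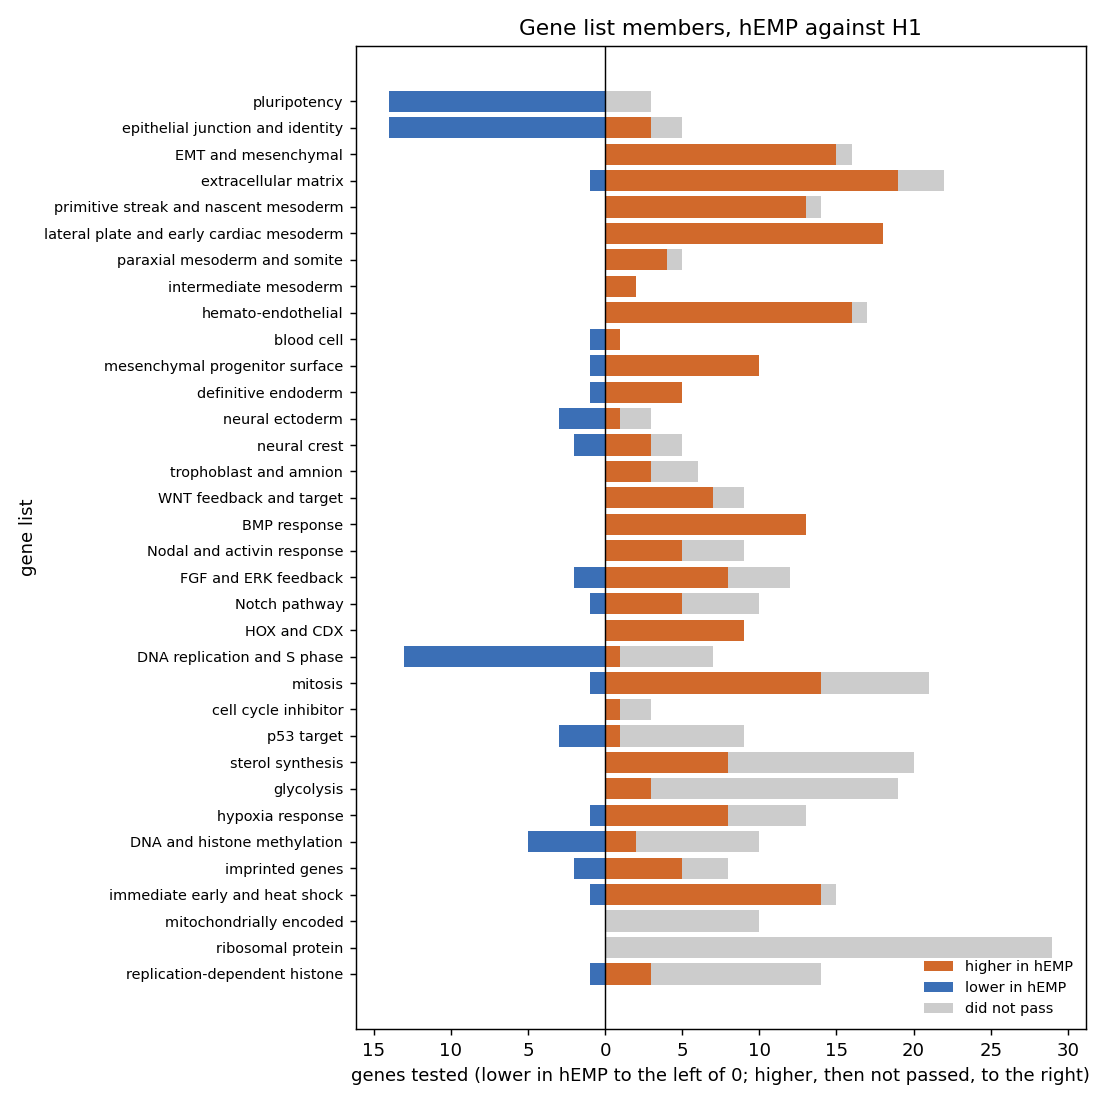
Number of tested genes of each of 34 lists that were lower in hEMP (left of 0), higher in hEMP or did not pass an adjusted p of 0.05 (right of 0). All 18 tested genes of lateral plate and early cardiac mesoderm were higher and 14 of 17 pluripotency genes lower; the bars of mitosis and ribosomal protein genes change with the scaling, to 7 higher and 2 lower and to 14 lower with median-of-ratios scaling.

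Primitive streak and nascent mesoderm genes rose for 13 of 14 members, with a median log2 change of 2.60, or 5.59 by limma-voom, which called 12 of 13 (13 adjusted over the list alone; camera adjusted p = 3.4e-09, and adjusted p = 0.19 with an estimated correlation). LHX1 went from 0.174 ± 0.0318 to 29.8 ± 7.3 RPKM. CYP26A1, which encodes a retinoic acid-degrading enzyme, did not pass, and its H1 values were 13.3, 0.68 and 46.6 RPKM in replicates 1 to 3. Without H1 replicate 2 its log2 change turned from 0.11 to -1.20 (adjusted p = 0.042, range over its alternatives 0.042 to 1). The 18 lateral plate and early cardiac genes had the highest median of the lists tested, 4.52, or 7.73 by limma-voom (18 adjusted over the list alone; camera adjusted p = 2.4e-13, and adjusted p = 0.19 with an estimated correlation). GATA6, BMP4 and MSX1 went from 0.217 ± 0.155 to 60.4 ± 4.45 RPKM, from 1.09 ± 0.129 to 98.7 ± 4.76 RPKM and from 0.145 ± 0.151 to 44.7 ± 4.53 RPKM. Of the paraxial mesoderm and somite list, 5 of 19 members were expressed highly enough to test, and 4 rose (5 adjusted over the list alone; camera adjusted p = 0.002, and adjusted p = 0.26 with an estimated correlation). DLL3 and FOXC1 rose from 0.795 ± 0.322 to 14.7 ± 1.42 RPKM and from 0.0336 ± 0.0127 to 6.58 ± 1.93 RPKM. The 2 tested genes of intermediate mesoderm, LHX1 and SALL1, both rose (2 adjusted over the list alone), too few for a list test. Of 42 HOX and CDX genes 9 could be tested and all 9 rose, by a median of 2.63, or 7.64 by limma-voom, which called 7 of 8 (9 adjusted over the list alone; camera adjusted p = 2.2e-06, and adjusted p = 0.26 with an estimated correlation), or 8 of 9 with upper-quartile scaling. Another 32 were in the table below the filter, 25 of them under 1 RPKM in every library. A gene near 0 in H1 can be tested only if it is higher in hEMP, which holds for every list. Those with the largest changes came from the HOXB cluster, with HOXB9 from 0.0207 ± 0.018 to 11.3 ± 1.47 RPKM and HOXB2 from 0.0108 ± 0.0187 to 8.15 ± 1.63 RPKM.

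Haemato-endothelial genes rose for 16 of 17 members, with a median log2 change of 1.75, or 4.39 by limma-voom (16 adjusted over the list alone; camera adjusted p = 3.6e-07, and adjusted p = 0.27 with an estimated correlation). TAL1 and GATA2, transcription factors of early blood, went from 0.121 ± 0.0661 to 13.8 ± 6.41 RPKM and from 0.0321 ± 0.0122 to 12.7 ± 1.07 RPKM, SOX7 from 0.56 ± 0.179 to 22.1 ± 8.94 RPKM and LMO2 from 0.877 ± 0.27 to 17.9 ± 6.33 RPKM. TEK did not pass (5.27 ± 3.1 RPKM in H1 and 8.39 ± 4.62 RPKM in hEMP), and passed without H1 replicate 2 (log2 change 0.95, adjusted p = 0.019, range over its alternatives 0.019 to 0.66). Of the 27 haemato-endothelial genes, another 9 were below the filter, 7 of them under 1 RPKM in every library. Of 18 blood cell genes, 2 could be tested (2 adjusted over the list alone). The progenitor gene MYB fell from 2.97 ± 1.64 to 0.444 ± 0.271 RPKM. Of 17 endoderm genes 6 could be tested and 5 rose (6 adjusted over the list alone; camera adjusted p = 0.0031, and adjusted p = 0.22 with an estimated correlation). The risers CER1, GATA6, GATA4, CXCR4 and HHEX are shared with mesoderm or blood vessels. The other 11 were below the filter, 9 of them under 1 RPKM in every library. SOX17, also in the haemato-endothelial list, was at 3.36, 0.879 and 2.65 RPKM in hEMP replicates 1 to 3. APOA2 was at 0.823, 1.15 and 1.94 RPKM there. In H1 these genes reached at most 0.145 and 0.061 RPKM. Whether the hEMP libraries held endoderm was not tested. FOXA3 fell, a call lost by limma-voom and without H1 replicate 2. Neural ectoderm genes were lower for 3 of 6 members and higher for 1, NES (4 adjusted over the list alone; camera adjusted p = 0.022, and adjusted p = 0.42 with an estimated correlation). NES lost its call under 11 of 16 alternatives (adjusted p 0.013 to 0.25), and a further member became lower with median-of-ratios scaling. The list lost its call with upper-quartile scaling (adjusted p = 0.063, range over the alternatives 0.0033 to 0.41). Another 14 of the 21 neural ectoderm genes were below the filter, 11 of them under 1 RPKM in every library. SOX3 fell from 2.74 ± 0.488 to 0.045 ± 0.0509 RPKM and ZIC2 from 39.9 ± 26.7 to 8.37 ± 3.84 RPKM. OTX2 did not pass (33.7 ± 23.1 RPKM in H1 and 17.7 ± 3.6 RPKM in hEMP) and was lower without H1 replicate 2 (log2 change -1.25, adjusted p = 0.00099, range over its alternatives 0.00099 to 0.75). Neural crest genes went both ways, 3 of 7 higher, led by SNAI2, and 2 lower, FOXD3 and ERBB3, with no call for the list (5 adjusted over the list alone; camera adjusted p = 0.57). Trophoblast and amnion genes were higher for 3 of 6 members, GATA2, GATA3 and ISL1, which mesoderm also expresses, with no call for the list (3 adjusted over the list alone; camera adjusted p = 0.15). Another 10 of the 19 trophoblast and amnion genes were below the filter, 7 of them under 1 RPKM in every library. ISL1 rose from 0.0265 ± 0.0459 to 29.8 ± 9.09 RPKM. The trophoblast gene TEAD4 did not pass (3.6 ± 1.21 RPKM in H1 and 2.79 ± 0.661 RPKM in hEMP).

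The BMP response list rose as a whole, with a median log2 change of 3.59 over its 13 tested members (13 adjusted over the list alone; camera adjusted p = 1.7e-09, and adjusted p = 0.19 with an estimated correlation). BAMBI, a decoy receptor gene induced by BMP, went from 5.37 ± 1.18 to 176 ± 13.8 RPKM, MSX2 from 0.309 ± 0.332 to 48.3 ± 14.1 RPKM and GATA3 from 0.0844 ± 0.0343 to 20.6 ± 6.57 RPKM. WNT targets and feedback genes rose for 7 of 9 members, with a median of 2.07, or 3.24 by limma-voom (7 adjusted over the list alone; camera adjusted p = 0.00017, and adjusted p = 0.22 with an estimated correlation). LGR5 rose from 0.113 ± 0.0435 to 27.2 ± 5.55 RPKM and LEF1 from 0.445 ± 0.287 to 16.3 ± 1.78 RPKM. AXIN2 did not pass (5.13 ± 2.09 RPKM in H1 and 7.47 ± 1.6 RPKM in hEMP). Of 9 Nodal and activin response genes 5 rose (5 adjusted over the list alone; camera adjusted p = 0.022, and adjusted p = 0.34 with an estimated correlation), led by CFC1 and CER1. The call was lost without H1 replicate 3 (adjusted p = 0.061, range over the alternatives 0.0021 to 0.061). SKIL did not pass (52.8 ± 18.9 RPKM in H1 and 56.6 ± 7.62 RPKM in hEMP). FGF and ERK feedback genes were higher for 8 of 14 members and lower for 2, FGF2 and ETV4, with no call for the list (10 adjusted over the list alone; camera adjusted p = 0.051). The list passed under 11 of 16 alternatives, among them the fits without H1 replicate 2 (adjusted p = 0.0066) and without hEMP replicate 2 (adjusted p = 0.049, range over the alternatives 0.0066 to 0.08). The ERK phosphatase genes DUSP6 and DUSP5 rose from 7.51 ± 3.44 to 81.3 ± 9 RPKM and from 3.16 ± 1.21 to 37.8 ± 7.37 RPKM, and FGF2 fell from 43.1 ± 5.42 to 4.17 ± 0.0961 RPKM. Notch pathway genes were higher for 5 of 11 members and lower for 1, NRARP, or for 4 and 3 of 12 with median-of-ratios scaling, with no call for the list (7 adjusted over the list alone; camera adjusted p = 0.23). HEY1, a target shared with BMP, rose from 0.402 ± 0.154 to 16 ± 2.93 RPKM, and JAG1 did not pass (7.71 ± 3.36 RPKM in H1 and 7.44 ± 2.22 RPKM in hEMP).

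Of 20 DNA replication and S phase genes, 13 were lower and 1, TYMS, was higher in hEMP, or 16 and 0 with median-of-ratios scaling (15 adjusted over the list alone; camera adjusted p = 4.6e-05, and adjusted p = 0.42 with an estimated correlation). The replicative helicase genes MCM5 and MCM3 fell from 10 ± 0.466 to 3.56 ± 1.12 RPKM and from 69 ± 2.02 to 30 ± 7.09 RPKM, and the polymerase gene POLA1 from 17.4 ± 1.54 to 7.81 ± 0.43 RPKM. RRM2 did not pass (42 ± 20.3 RPKM in H1 and 31.8 ± 7.99 RPKM in hEMP). MCM2, lower in the full comparison, lost its call without hEMP replicate 2 (log2 change -0.68, adjusted p = 0.061) or hEMP replicate 3 (-0.75, adjusted p = 0.056, range over its alternatives 0.00037 to 0.061). Of 22 mitosis genes, 14 were higher and 1, BUB1B, was lower, or 7 and 2 with median-of-ratios scaling and 6 and 3 with upper-quartile scaling, with no call for the list (15 adjusted over the list alone; camera adjusted p = 0.061). That list passed under 5 of 16 alternatives, among them the fits without H1 replicate 2 (adjusted p = 0.036), hEMP replicate 2 (0.041) and hEMP replicate 3 (0.048, range over the alternatives 0.015 to 0.15). KIF20A rose from 23.8 ± 3.87 to 48.1 ± 1.07 RPKM and MKI67 from 24.3 ± 1.31 to 45.5 ± 5.28 RPKM, and BUB1B fell from 49.7 ± 2.7 to 27.2 ± 4.73 RPKM. CENPF did not pass (86.9 ± 6.41 RPKM in H1 and 79.9 ± 2.66 RPKM in hEMP). Of 3 cell cycle inhibitor genes CDKN1C rose, from 1.74 ± 0.96 to 6.33 ± 2.81 RPKM (1 adjusted over the list alone; camera adjusted p = 0.74), and CDKN1B did not pass (9.27 ± 3.05 RPKM in H1 and 8.94 ± 2.33 RPKM in hEMP). Of 12 p53 targets 1, SESN2, was higher and 3 were lower, or 1 and 6 with median-of-ratios scaling and 0 and 6 with upper-quartile scaling, with no call for the list (4 adjusted over the list alone; camera adjusted p = 0.082), although it passed without H1 replicate 2 (adjusted p = 0.036, range over the alternatives 0.015 to 0.24). SESN2 lost its call under 5 of 15 alternatives (adjusted p 0.02 to 0.1). RRM2B fell from 10.1 ± 0.802 to 3.75 ± 0.445 RPKM. Replication-dependent histone genes, a multigene family of near copies, were higher for 3 of 15 members and lower for 1, HIST3H2A, or 1 and 0 by limma-voom (4 adjusted over the list alone; camera adjusted p = 0.99). HIST3H2A lost its call under 4 of 14 alternatives and HIST1H1C, 1 of those higher, under 7 of 15.

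**Figure D3:**
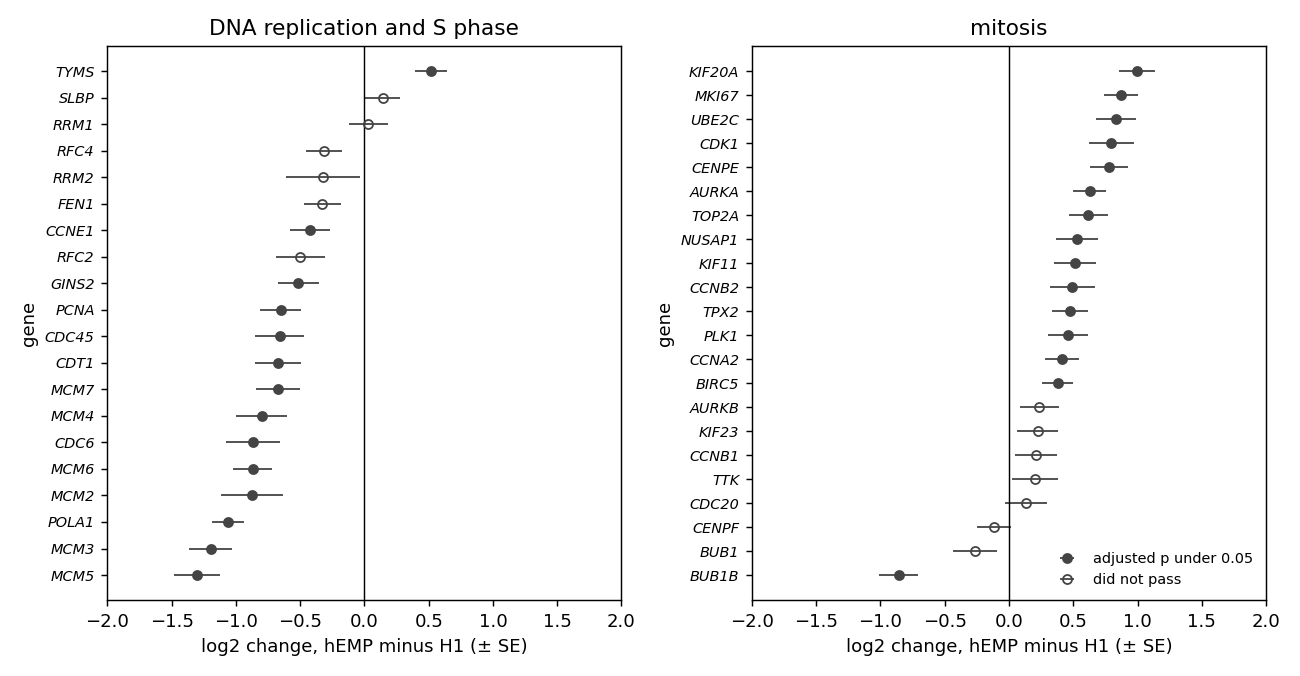
Log2 change, hEMP minus H1, with its SE for each tested gene of the DNA replication and S phase list (20 genes) and the mitosis list (22 genes); filled points passed an adjusted p of 0.05. With the deposited scaling 13 replication genes lie below 0 and 14 mitosis genes above 0 past the threshold, against 16 and 7 with median-of-ratios scaling.

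Sterol synthesis genes were higher for 8 of 20 members, 5 with median-of-ratios scaling and 12 without H1 replicate 2, and lower for none, with no call for the list (8 adjusted over the list alone; camera adjusted p = 0.20). Without H1 replicate 2 the list was called (adjusted p = 0.0033, range over the alternatives 0.0033 to 0.64). STARD4, which encodes a sterol transfer protein, rose from 9.34 ± 2.81 to 19.4 ± 1.3 RPKM, and INSIG1 from 5.34 ± 1.56 to 10.6 ± 2.53 RPKM. Glycolysis genes were higher for 3 of 19 members, SLC16A3, PKM and PFKP, and lower for 0, or 1 with median-of-ratios scaling and 3 without H1 replicate 2, with no call for the list (3 adjusted over the list alone; camera adjusted p = 0.73). GAPDH did not pass (751 ± 141 RPKM in H1 and 726 ± 138 RPKM in hEMP). Hypoxia response genes were higher for 8 of 14 members and lower for 1, ADM (10 adjusted over the list alone; camera adjusted p = 0.031, and adjusted p = 0.65 with an estimated correlation). The list call was lost with a filter at 5 RPKM (adjusted p = 0.086, range over the alternatives 0.0074 to 0.086). The collagen prolyl hydroxylase genes P4HA1 and P4HA2 rose from 18 ± 9.14 to 109 ± 30.5 RPKM and from 1.3 ± 0.804 to 8.62 ± 1.92 RPKM. BNIP3 did not pass, and its H1 values were 66.0, 10.5 and 61.5 RPKM in replicates 1 to 3. Of 15 genes for DNA and histone methylation, 5 were lower and 2 higher, with no call for the list (7 adjusted over the list alone; camera adjusted p = 0.075), although it passed without H1 replicate 2 (adjusted p = 0.049, range over the alternatives 0.014 to 0.12). The de novo methyltransferase gene DNMT3B fell from 207 ± 23.3 to 36 ± 11.6 RPKM and JARID2 from 64.1 ± 10.1 to 22 ± 0.754 RPKM. TET2 rose from 1.29 ± 0.416 to 4.02 ± 0.527 RPKM, and KDM1A did not pass (102 ± 15.2 RPKM in H1 and 94.8 ± 4.21 RPKM in hEMP). Of 10 imprinted genes 5 were higher and 2, SNRPN and GRB10, lower (8 adjusted over the list alone; camera adjusted p = 0.19), led by PLAGL1 from 0.274 ± 0.119 to 20 ± 5.09 RPKM and the growth factor gene IGF2 from 0.223 ± 0.0555 to 11.7 ± 2.84 RPKM.

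Immediate early and heat shock genes, a list that also follows cell handling, were higher for 14 of 16 members (15 adjusted over the list alone; camera adjusted p = 0.00017, and adjusted p = 0.22 with an estimated correlation). FOS, FOSB and EGR3 rose from 6.8 ± 1.81 to 33 ± 15.8 RPKM, from 0.19 ± 0.113 to 4.36 ± 0.0596 RPKM and from 0.44 ± 0.368 to 9.77 ± 3.69 RPKM. The chaperone gene HSPH1 fell from 47.4 ± 9.11 to 22.2 ± 2.88 RPKM. HSPA1A, which shares reads with its copy HSPA1B, did not pass (4.28 ± 1.32 RPKM in H1 and 5.8 ± 0.806 RPKM in hEMP). The labels name a sort for hEMP and none for H1. Of 10 mitochondrially encoded genes, limma called 0 at an adjusted p and 0 at an unadjusted p under 0.05, against 1 lower by limma-voom and 2 higher without H1 replicate 2 (0 adjusted over the list alone; camera adjusted p = 0.47). Ribosomal protein genes had a median log2 change of -0.27, or -0.41 relative to all genes, and limma called 0 of 29, with 1 at an unadjusted p under 0.05, against 14 lower with median-of-ratios scaling, 18 with upper-quartile scaling, 17 by limma-voom and 16 without H1 replicate 2 (0 adjusted over the list alone; camera adjusted p = 0.0066, and adjusted p = 0.65 with an estimated correlation). The list call was lost without H1 replicate 1 (adjusted p = 0.05, range over the alternatives 8.5e-05 to 0.05). Mitochondrial transcripts made up 1.5%, 3.1% and 1.5% of the reads in H1 replicates 1 to 3 and 1.6%, 2.0% and 1.1% in hEMP replicates 1 to 3. Without H1 replicate 2, the library with the highest share, 5276 genes changed, 3143 higher and 2133 lower.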

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

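The limma-voom and GC and length results, the lists without the sort markers (19 called), and the scaling, filter and pseudocount results for lists and their members, were chosen after the data were seen. No alternative gave a gene a call opposite to the one reported, and of the values of named genes under the alternatives, 2310 stayed on their side of the threshold, 39 fell short of it, 31 came past it and 1 reversed. That was CYP26A1 without H1 replicate 2, at a log2 change of -1.20 (adjusted p = 0.042, range over its alternatives 0.042 to 1), and its log2 change without each library ran from -1.20 to 1.21. Genes called lower numbered 2907 with upper-quartile scaling and 2863 with the GC and length trend removed, against 1835, and these settings shift the median log2 change of all genes from 0.14 to -0.05 by their construction. A filter at 5 RPKM tested 5735 genes and called 2991, 1925 higher, 1066 lower and 1061 at least 2-fold. The 2-fold count was 2488 with a pseudocount of 0.1, 2433 by limma-voom, 651 with a pseudocount of 5, which shrinks changes of low values, and 740 against a log2 change of 1, a stricter test. Lists past the threshold numbered 0 with an estimated correlation, where camera has few degrees of freedom because they come from the libraries. The lowest camera adjusted p there was 0.19, also for EMT and mesenchymal genes, whose estimated correlation was 0.06. Estimated correlations ran from -0.04 to 0.91 over the lists. How far correlation between genes itself lowered the calls was not tested.

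Leaving out each library in turn gave 3931 to 5276 genes changed, 2469 to 3143 higher, 1404 to 2133 lower, 1718 to 1871 at least 2-fold, 235 to 298 list members and 18 to 24 lists. Of the 19 lists called, 15 passed under every one of the 16 refits in which they could be tested, which for paraxial mesoderm and somite was 15. The exceptions were neural ectoderm (12 of 16, adjusted p up to 0.41), Nodal (14 of 16, up to 0.061), hypoxia (15 of 16, up to 0.086) and ribosomal protein genes (14 of 15, up to 0.05). Of the lists not called, FGF and ERK feedback passed under 11 of 16 refits, mitosis under 5, DNA and histone methylation under 3, p53 targets under 2, and trophoblast and amnion, Notch and sterol synthesis under 1 each. With the replicate number as a block, 5242 genes changed, 3323 higher and 1919 lower, with 1772 at least 2-fold, 286 list members and 21 lists. The correlations across genes of deviations from the group mean were 0.04, 0.03 and 0.21 between libraries of the same number and -0.26 to 0.17 between the others, so the numbers were not taken as pairs. Planned count-based alternatives (TMM factors, a Wald test, a count-based fold test) were not run, since the values are not counts, and library totals and the count filter are already those reported. Differences below 0.098 to 0.162 RPKM, 3 reads for a 2 kb gene, were not detectable at this depth.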

Other observations

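Metallothionein genes, whose products bind zinc and copper, were lower in hEMP. They and the other gene families, and the genes that differ within a group, were chosen after the data were seen, as were the tests on residual undifferentiated cells and on immediate early genes. All 6 tested members fell, MT1H from 31.9 ± 19.1 to 0.955 ± 0.276 RPKM, MT1X from 27.8 ± 19.1 to 4.04 ± 1.28 RPKM, MT1G from 15.3 ± 10.5 to 1.06 ± 0.126 RPKM, MT2A from 10.1 ± 4.95 to 1.31 ± 0.585 RPKM, MT1E from 9.94 ± 6.15 to 0.925 ± 0.351 RPKM and MT1F from 2.37 ± 1.28 to 0.335 ± 0.0614 RPKM (n = 3), with log2 changes between -3.86 and -1.26. H1 replicate 2 was the lowest H1 library for each, at 11.6 RPKM for MT1H against 49.5 and 34.7 in H1 replicates 1 and 3, and reads may be shared among these copies, which was not tested. Families were formed from gene symbols with at least 5 tested members, a minimum lowered from 8 after a first look, and 320 were tested. Of these 11 passed, 6 of them higher (HOXB, GATA, WNT, TBX, COL and KLF) and 5 lower (SYT, MT, MCM, CLDN and RPL), and each had an adjusted p of 1 with an estimated correlation. The metallothionein family had a camera adjusted p of 0.005 (adjusted p = 1 with an estimated correlation), against 0.00082 for HOXB, the lowest. Synaptotagmin genes, which encode calcium sensors of membrane fusion, were lower for 7 of 8 members (camera adjusted p = 0.005, and adjusted p = 1 with an estimated correlation). These family counts were not repeated under other scalings. The filter in part set the rises of families near 0 in H1, such as HOXB and GATA, whose members could be tested only if higher in hEMP.

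Some genes differed widely within a group, and they were not tested as a set. In H1 replicates 1, 2 and 3, SIX3 was at 0.53, 0.03 and 7.08 RPKM, FEZF1 at 1.46, 0.39 and 9.23 RPKM, LHX5 at 1.75, 0.05 and 7.74 RPKM and OTX2 at 31.8, 11.7 and 57.7 RPKM. TXNIP, a gene regulated by glucose, was at 30.8, 2.19 and 25.2 RPKM, and DDIT4 at 31.8, 5.33 and 67.4 RPKM. In hEMP replicates 1, 2 and 3, CDH5 was at 6.06, 1.60 and 2.01 RPKM, ERG at 5.08, 1.91 and 1.97 RPKM and CD34 at 4.73, 1.58 and 2.27 RPKM.

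The 6 libraries make 10 splits into 3 and 3, which cannot give a share under 0.1. The real split gave 5087 genes changed, 3252 higher, 1835 lower, 1770 at least 2-fold and 264 list members, the highest other split gave 0 of each, and 1 of 10 splits gave as many in each case. It gave 19 lists against 23 in the highest other split, and 4 of 10 splits gave as many. Every other split mixes H1 and hEMP on both sides, so the group difference adds to its spread and hides single genes. The 0 calls there therefore do not show what chance would give, and the lists called there can carry the group difference.

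With the deposited scaling 13 of 20 replication genes were called lower in hEMP and 14 of 22 mitosis genes higher, with BUB1B lower and no call for the mitosis list, and with median-of-ratios scaling 7 mitosis genes were higher and 2 lower. The mean log2 gap between mitotic and replication genes within a library, which no scaling factor moves, was 0.35, 0.27 and 0.34 in H1 and 1.13, 1.38 and 1.31 in hEMP, a difference of 0.96, which argues against library scaling as the whole cause of the gap. The gap between the medians of the lists was 1.12, and 1.1 with the GC and length trend removed, which argues against that trend as the whole cause. Without H1 replicate 2, the library with the highest mitochondrial share, it was 1.06. A difference in cell cycle between the cell states stays open, as untested.

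Some pluripotency transcripts were left in hEMP, and undifferentiated cells left in the sorted population may carry them. The sort against CD326, which H1 cells express, would remove such cells, and any left would bring all their transcripts in one ratio. Of the 13 other called members, 11 kept in each hEMP library a larger share of their H1 level than the 5.1% that SOX2 kept at most, among them LIN28A (39.5% ± 5.2) and SALL4 (60.1% ± 11), which argues against such cells as the whole cause. The exceptions were NANOG (4.5% to 7.7%) and FOXD3 (4.0% to 4.9%), for which such cells stay open. Within hEMP replicates 1 to 3, NANOG kept 7.7%, 6.0% and 4.5% and SOX2 kept 5.1%, 2.9% and 2.9%. FOXD3 rests on an estimated 11 reads over the hEMP libraries. Slower loss of these transcripts in the hEMP cells themselves was not tested.

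Immediate early genes were higher in hEMP. All 14 list members called higher kept the call with median-of-ratios scaling. That scaling moved the list's median log2 change only from 1.53 to 1.42, so the calls could hardly be lost. The small shift argues against the choice between these scalings as the cause. The labels name a sort for hEMP and none for H1, so handling and cell state cannot be told apart. Of 3 heat shock members 1, DNAJB1, was called higher, which excludes neither.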
